A study of Mus musculus with 2 samples.

How the data were processed

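DNA methylation was measured by whole-genome bisulfite sequencing in 2 libraries, 1 from CD137+ and 1 from PDGFRα+ (CD140+) adipose progenitors of C57BL/6 mice. Per the labels' protocols, the cells were sorted magnetically, cultured, differentiated and treated with 1 µM dexamethasone, and DNA was sheared to fragments of about 350 bases before conversion and library amplification. The labels assign each library to its group by its title.

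The data used are 1 table of differentially methylated regions with 10 columns, made by the authors. Per the file headers, it gives the position of each region, its length, its number of cytosines, the methylation level in each library, the difference between them, an area statistic and the direction. The methylation level is deposited as a fraction from 0 to 1 for each library. The difference is deposited as the level in CD140 minus the level in CD137, and it equals the difference of the deposited levels within 0.0002 in all 28141 regions. The area statistic is deposited as a score with no fixed range, and in 2 regions its sign is opposite to that of the difference. The number of cytosines and the length are deposited as whole numbers, and the length equals the end minus the start in every region. The genome build is mm10, per the submitters' processing notes. The aligner, the methylation caller, the region caller, its thresholds, the coverage minimum and the sequence context of the cytosines are not given in the sources used here. Read counts per region were not used here, so the depth of each library is unknown, and a level cannot be given an interval. The authors' filter keeps only regions called as different, so shares and medians describe those regions, and only 199 of them (0.707%) had an absolute difference under 0.3.

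Each region was assigned to every gene whose span it overlaps or lies within 2 kb of, on either side, from RefSeq gene spans on GRCm38.p6, the assembly of mm10. The planned rule, 2 kb upstream of the start, needed the strand of genes, and strand and exons were not used here, so the flank was taken on both sides and promoters, exons and introns were not separated. All 460 symbols of the 17 gene lists fixed before the data were examined matched a gene (13 pathway lists and 4 lists of markers of other cell types). A further 7 lists with 172 symbols were written after the results of the fixed lists were seen. A list member was called mostly higher or mostly lower by the direction of most of its regions.

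Regions were counted by direction, with a Wilson 95% interval for shares, which covers counting error only and treats regions as independent. No test between groups was made, since each group had 1 library. A list was compared with 10000 random lists of protein-coding genes of the same size, matched on gene length in 10 classes, by its number of members with a region, its share of higher regions and the median over members of the mean difference. A list outside the central 95% (percentiles 2.5 to 97.5) is called. The percentile describes these libraries and is not a p-value, and the cytosine content of genes was not matched. The location of regions was compared with 1000 random placements of regions with the same lengths on the same chromosomes. For the named genes the rule, fixed beforehand, was Tead1 always, the 10 regions of each direction with the largest absolute statistic at a named protein-coding gene with at most 1 region per gene, up to 4 members of each list with the top regions, and the 5 genes with the most regions, where a tie for the last place brought in 8. Gene models of unnamed kinds were left out, and not every item that the rule selects is reported here. Genes named outside this rule, such as further members of the lists, were chosen after their values were seen.

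Alternatives covered minimum differences of 0.3 and 0.5, minimums of 5 and 10 cytosines, the regions with an absolute statistic above the median, autosomes only, weighting by length or by cytosines, merging of neighbouring regions, other flanks and overlap rules, and random lists without length matching. The overlap search gave 0 differences from a brute-force search over 300 genes. The list comparison was tested on the real regions with directions redrawn at random, using lists of 25 protein-coding genes. With every region of their genes set higher, an extreme case, 100% of 100 lists were called. Of 400 unchanged lists, 4.5% fell outside the central 95% in median difference. Directions were redrawn for each region separately, so the test does not cover directions that cluster within genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.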

Results

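Whole-genome bisulfite sequencing was used to compare DNA methylation in 2 populations of adipose progenitors from C57BL/6 mice. In this assay unmethylated cytosines are converted and methylated ones are not, so the methylation level of a region is the fraction of its cytosines read as methylated. One library came from cells sorted for CD137, a surface receptor of the tumour necrosis factor receptor family used as a marker of beige adipocyte precursors. The other came from cells sorted for PDGFRα (CD140), a receptor for platelet-derived growth factor found on mesenchymal progenitors. Both populations had been cultured, exposed to an adipogenic cocktail and treated with 1 µM dexamethasone, a synthetic glucocorticoid. Cells came from subcutaneous or visceral fat, and which depot gave which library was not stated. With 1 library per group, no difference reported here has a replicate check, and no p-value is given. The read depth behind the levels is unknown, so levels are given without intervals.

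The comparison asked where the PDGFRα+ library differed in methylation from the CD137+ library, both treated with dexamethasone. No untreated library was compared, so an effect of dexamethasone on methylation cannot be seen here. Most of the regions listed by the authors were less methylated in PDGFRα+ cells. Of 28141 differentially methylated regions, 21870 (77.7%) were lower in the PDGFRα+ library and 6271 (22.3%, 95% Wilson interval 21.8 to 22.8) were higher, a ratio of 3.49. In regions lower in PDGFRα+ cells the median level was 0.261 in PDGFRα+ and 0.820 in CD137+, with a median difference of -0.527. In regions higher in PDGFRα+ cells the median levels were 0.879 and 0.344, with a median difference of 0.507. Differences of at least 0.6 made up 24.7% of the lower regions (5396) and 18.8% of the higher regions (1178). The regions covered 7.28 Mb and 314272 cytosines, with a median length of 216 bases and a median of 9 cytosines. The interval covers counting error only, and only regions called as different were listed, so levels elsewhere in the genome are not known.

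**Figure D1:**
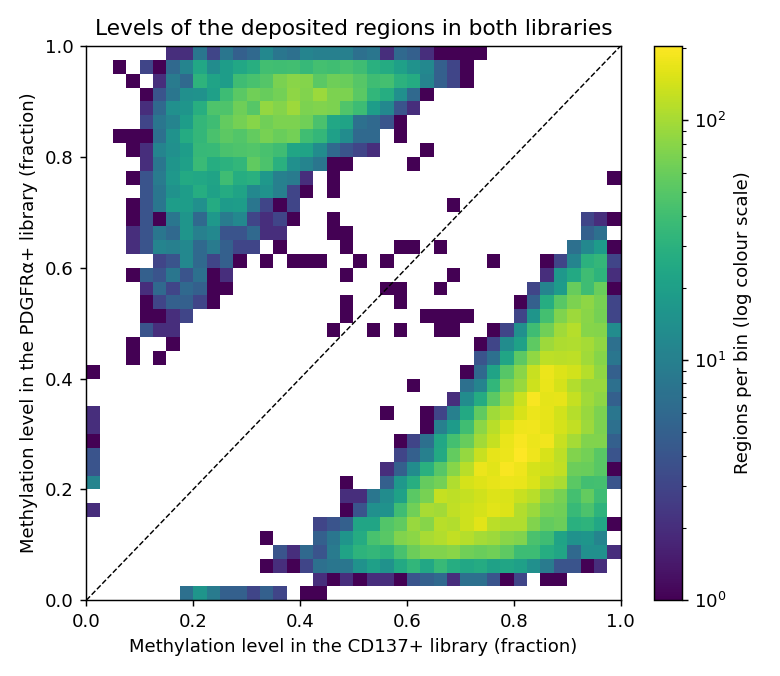
Methylation level of each region in the CD137+ library (x axis, fraction) against the PDGFRα+ library (y axis, fraction), with colour giving the number of regions per bin on a log scale and the dashed line marking equal levels. The larger cloud, 21870 regions below the line, was less methylated in PDGFRα+ cells, and the smaller cloud, 6271 regions above it, was more methylated.

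Tead1 encodes a transcription factor that acts at the end of the Hippo pathway, and its methylation is the subject named for this study. More regions of the gene were higher than lower in PDGFRα+ cells. Within the gene span, chromosome 7 from 112679356 to 112906784 in mm10, 8 regions were listed, 5 higher and 3 lower in PDGFRα+. Starts are printed as deposited and may be off by 1 base, because the table does not show whether it counts from 0 or 1. The higher region nearest the lower end of the gene, 112685224 to 112685359, had a level of 0.701 in PDGFRα+ and 0.208 in CD137+. The region with the widest difference, 112859880 to 112860280, had levels of 0.916 and 0.304. The 3 lower regions lay next to each other, from 112731572 to 112788403. They started 52216 to 108950 bases from the lower end of the 227 kb gene. Their levels were 0.302, 0.341 and 0.444 in PDGFRα+ against 0.840, 0.837 and 0.957 in CD137+. The mean difference over the 8 regions was 0.109. Among 2189 protein-coding genes of similar length, the number of higher regions in Tead1 stood at the 98.0 percentile and the number of regions of either direction at the 86.7 percentile, and 58 of these genes had at least 5 higher regions. With only differences of at least 0.5 kept, 5 regions remained, of which 3 were higher. Within 50 kb on either side lay 2 further regions, a lower one at 112644630 to 112644815 and a higher one at 112935997 to 112936208. Tead1 is named as the subject of the study that these samples come from, and how it was chosen is not known here. Its direction is therefore not taken as independent evidence. Whether a region lies in an exon, an intron or a promoter is not given, because exons and gene strand were not used here.

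**Figure D2:**
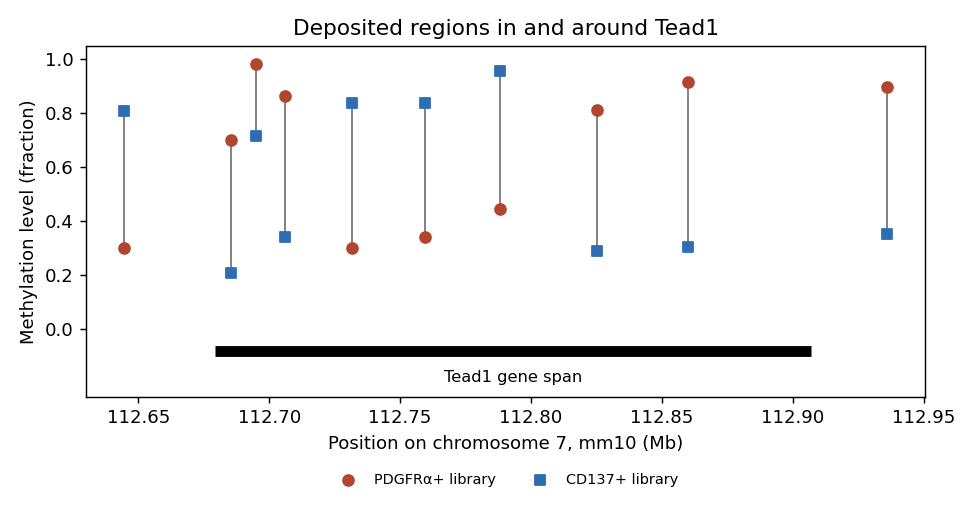
Methylation level (fraction, y axis) of each listed region in and within 50 kb of Tead1 along chromosome 7 (x axis, Mb in mm10), with circles for the PDGFRα+ library and squares for the CD137+ library joined by a line, and the black bar marking the gene span. Of the 8 regions in the gene, 5 were higher in PDGFRα+, and the 3 lower ones were neighbours, starting 52216 to 108950 bases from the lower end of the gene.

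The genes of the sorting markers were also examined. Pdgfra held 1 region, chromosome 5 from 75185945 to 75186093, with a level of 0.210 in the PDGFRα+ library and 0.769 in the CD137+ library. Tnfrsf9, the gene of CD137, held none within 2 kb, and the nearest region lay 48308 bases away.

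The region with the largest negative statistic lay in or within 2 kb of Hoxa3, Hoxa5 and Hoxa6, homeobox genes of body patterning (chromosome 6, 52203837 to 52205404). Its levels were 0.185 in PDGFRα+ and 0.665 in CD137+. Next came Gimap1, a GTPase gene of lymphocytes (0.234 against 0.775), and Nfia, a transcription factor gene (0.132 against 0.756). Syne2, encoding a nuclear envelope protein, had levels of 0.190 and 0.809. The largest positive statistic belonged to a region in Nbea that lies also at Mab21l1 (chromosome 3, 55782346 to 55784418), with levels of 0.842 in PDGFRα+ and 0.324 in CD137+. A region 1245 bases outside Lyl1, a transcription factor gene of blood cell development, had levels of 0.849 in PDGFRα+ and 0.202 in CD137+. That region lay also in or within 2 kb of Nfix. A region of Lcp1, which encodes an actin-bundling protein of leukocytes, had levels of 0.836 in PDGFRα+ and 0.280 in CD137+. The higher regions also included those of Tnxb, which encodes a matrix glycoprotein (0.844 against 0.324), and Osr1, a transcription factor gene of mesenchyme (0.803 against 0.276). Others lay 1902 bases outside Meis2 (0.936 against 0.420) and in the splicing regulator gene Mbnl1 (0.926 against 0.252). Ehbp1 (0.913 against 0.249) and Fam117a (0.871 against 0.308) completed this direction together with Hps4. Over all their regions, Tnxb (1 higher, 2 lower), Meis2 (2 and 4), Ehbp1 (2 and 6) and Fam117a (3 and 4) were mostly lower. Nbea was nearly even (6 and 5). Lyl1 (2 and 0), Lcp1 (2 and 1), Mbnl1 (6 and 2) and Osr1 (2 and 0) were mostly higher.

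Hps4 and 5 of the 10 lower regions were of another kind, with 1 library close to 0 and the other at a modest level. In Hps4 the levels were 0.236 in PDGFRα+ and 0.0089 in CD137+. In Dock9, Eya2, Cyrib, Tuft1 and Spop the PDGFRα+ levels lay between 0.0014 and 0.0055 and the CD137+ levels between 0.202 and 0.293. In all, 81 regions had 1 library below 0.02, with the other between 0.166 and 0.442. They held 21.7 cytosines per 100 bases at the median, against 4.61 in the other regions.

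Genes with many regions were mostly long genes in which lower regions prevailed, as they did over all regions (77.7%). Wwox, a putative tumour suppressor gene of 913 kb, held 39 regions, 30 of them lower in PDGFRα+. Adamtsl1 held 30 (26 lower), Nfia 29 (27 lower) and Foxp1, a forkhead transcription factor gene, 28 (20 lower). Dlc1 (20 lower), Ldlrad4 (16 lower) and Pde4d (17 lower) each held 24. Counted per 100 kb of gene, none of the 8 genes with the most regions was among the 8 highest. Of 21887 protein-coding genes, 6454 (29.5%) had a region in the gene or within 2 kb, 3775 with lower regions only, 1195 with higher regions only and 1484 with both. Of the 816 genes with at least 5 regions, 222 had every region lower and 10 had every region higher. Those 10, chosen after their values were seen, were Ptprc (8 regions), Hoxd3 and Jmjd1c (7 each), Ston2 (6), and Foxc1, Ikzf1, Itpkb, Serinc3, Tbx18 and Tbx2 (5 each). Tcf4, a basic helix-loop-helix transcription factor gene singled out in the same way, had 16 higher regions out of 17.

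Regions lay inside genes more often than random placement gave. Protein-coding gene spans held 52.5% of regions (95% Wilson interval 51.9 to 53.1), against a mean of 40.5% in 1000 random placements of the same lengths on the same chromosomes. Spans of other genes held 9.78% against 8.45%, and the 2 kb next to a gene held 4.57% against 4.53%, a value inside the range of the random placements. The share higher in PDGFRα+ was 28.2% (25.8 to 30.7) within 2 kb of a gene, 24.8% (24.1 to 25.5) in protein-coding spans and 17.0% (16.3 to 17.8) away from genes. Random placement did not take account of cytosine content or read coverage.

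Genes of Hippo signalling, of the glucocorticoid response and of the extracellular matrix had regions more often than length-matched random genes. Most of their members with a region were mostly lower in PDGFRα+ cells, as were most regions overall. In the Hippo and TEAD list, 21 of 31 genes had a region, at the 99.3 percentile of random lists, and 16 were mostly lower. Tead1, which is named as the subject of the study, is one of the 3 mostly higher members. Examples were Lats2, a kinase gene of the pathway (4 of 4 regions lower, mean level 0.256 in PDGFRα+ and 0.826 in CD137+), Vgll4, a TEAD cofactor gene (6 of 6 lower, 0.244 and 0.824), Ptpn14 (6 of 7 lower) and Ankrd1, a known target gene (0.227 and 0.737). The Hippo and TEAD call was lost when at least 10 cytosines were required and when only the gene ends were used. In the glucocorticoid response list, 16 of 25 genes had a region, at the 99.9 percentile, and 13 were mostly lower. Its members Crispld2 (3 of 3 regions higher, 0.926 and 0.387) and Nrip1 (3 of 4 higher) were the exceptions, while Nr3c2, the mineralocorticoid receptor gene, was lower in 5 of 5 regions (0.327 and 0.814) and Ncoa2 was split. In the extracellular matrix list, 31 of 37 genes had a region, at the 100 percentile, and 29 were mostly lower, among them Timp2 (5 of 5 regions, 0.246 and 0.866), Col5a1 (7 of 7, 0.275 and 0.869) and Mmp14 (2 of 2, 0.115 and 0.817), with Mmp2 higher (0.902 and 0.210). Only 9.89% of the matrix regions were higher, at the 2.18 percentile, but the median difference of the list, at the 5.94 percentile, lay inside the central 95% of random lists. The Hippo and glucocorticoid lists lay inside the central 95% in direction, with 22.9% and 22.2% of regions higher (50.2 and 49.6 percentiles, with 22.3% over all regions) and median differences at the 12.4 and 17.5 percentiles. With 10 kb on either side, the median difference of the glucocorticoid list lay below it, at the 2.10 percentile.

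Counted by gene, more of the patterning genes known to differ between fat depots were mostly higher than mostly lower in PDGFRα+ cells, while most of their regions were lower. Of the 40 genes, 23 had a region, at the 100 percentile, and 14 were mostly higher in PDGFRα+ and 8 mostly lower. The median difference was 0.352 against -0.439 in random lists, at the 99.7 percentile. Hoxd3 was higher in 7 of 7 regions (mean level 0.821 in PDGFRα+ and 0.315 in CD137+) and Tbx18 in 5 of 5 (0.849 and 0.412). Hoxa3, Hoxa5 and Meis1 were lower in every region, with 13, 5 and 8 regions. Of its 94 regions 62 were lower and 32 higher, and the share of higher regions over its genes, 33.7%, stood at the 81.5 percentile, inside the central 95%. Neighbouring Hox genes share regions. The span used for Hoxa3 contains that of Hoxa5, so the 5 regions of Hoxa5 are also among the 13 of Hoxa3. Random lists were drawn without regard to such neighbours, so the percentiles of this list compare linked genes with genes drawn separately. The direction call was lost when only differences of at least 0.5 were used, where the median was 0.00198, and with gene ends only, where it was 0.427.

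Adipocyte genes were mixed. In the white adipocyte list 15 of 33 genes had a region, at the 97.8 percentile, with 2 mostly higher, 6 mostly lower and 7 split evenly, and the call was lost under 3 alternatives, with at least 5 cytosines, with 10 kb on either side and with gene ends only. Fabp4, encoding the fatty acid carrier of adipocytes, Retn (resistin) and Gpd1 each had 1 region higher and 1 lower, while Zfp423, a preadipocyte transcription factor gene, was lower in 7 of 8. In the brown and beige adipocyte list 13 of 30 genes had a region, at the 67.7 percentile, and 10 were mostly lower, including Prdm16, a regulator of brown fat identity (15 of 16 regions, 0.335 and 0.788), and Ppargc1a, a regulator of mitochondrial biogenesis (11 of 14). The median differences of the white and of the brown and beige lists, -0.0705 and -0.341, stood at the 93.7 and 75.8 percentiles. Both medians turned positive with gene ends only, where just 7 and 2 members had a region.

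Circadian clock genes had regions in 16 of 20 members, at the 100 percentile, 12 of them mostly lower, including Rora (13 of 14 regions lower) and Npas2 (3 of 3), and the call was lost with gene ends only. In direction the clock list lay inside the central 95%, with its share of higher regions at the 26.7 percentile and its median difference at the 35.5 percentile. The other pathway lists lay inside the central 95% in the number of members with a region, although alternatives put several outside it. These were TGF-beta, BMP and Wnt signalling (22 of 37, with Tgfbr3 lower in 14 of 14 regions), insulin and lipid signalling (20 of 30, with Foxo3 lower in 5 of 5), imprinted genes (18 of 37, with Grb10 lower in 4 of 4 and Mest higher in its only region), progenitor and fibroblast genes (9 of 25, with Dcn lower in 6 of 6) and the DNA methylation machinery (6 of 20, with Tet1, Tet3, Dnmt3l and Gadd45a each lower in 1 region, Mbd2 higher in 1 and Tet2 split). The TGF-beta, BMP and Wnt list lay above the central 95% with at least 10 cytosines, with the larger statistics only and without length matching (99.9 to 99.99 percentile), insulin and lipid signalling and imprinted genes without length matching (100 and 99.2), and the DNA methylation machinery below it with at least 10 cytosines (1.70). With gene ends only the median difference of the insulin list turned from -0.340 to 0.411, but just 4 members then had a region. Of the ribosomal protein genes, taken as a comparison list, 1 of 28 had a region, Rpl18, so its median difference of 0.644, at the 99.3 percentile, rests on 1 gene, and it was -0.198 with 10 kb on either side. In members with a region this list lay below the central 95% with 10 kb on either side (1.98 percentile) and without length matching (0.035). Over the 13 lists, 6 lay above the central 95% in members with a region, and 2 lay above it in median difference, depot patterning and ribosomal protein. For lists drawn at random, 0.65 would lie outside, counting both sides. Matching was on gene length only, and 3 of the 4 marker lists of other cell types also lay above in members with a region. The excess is thus not particular to these pathways.

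**Figure D3:**
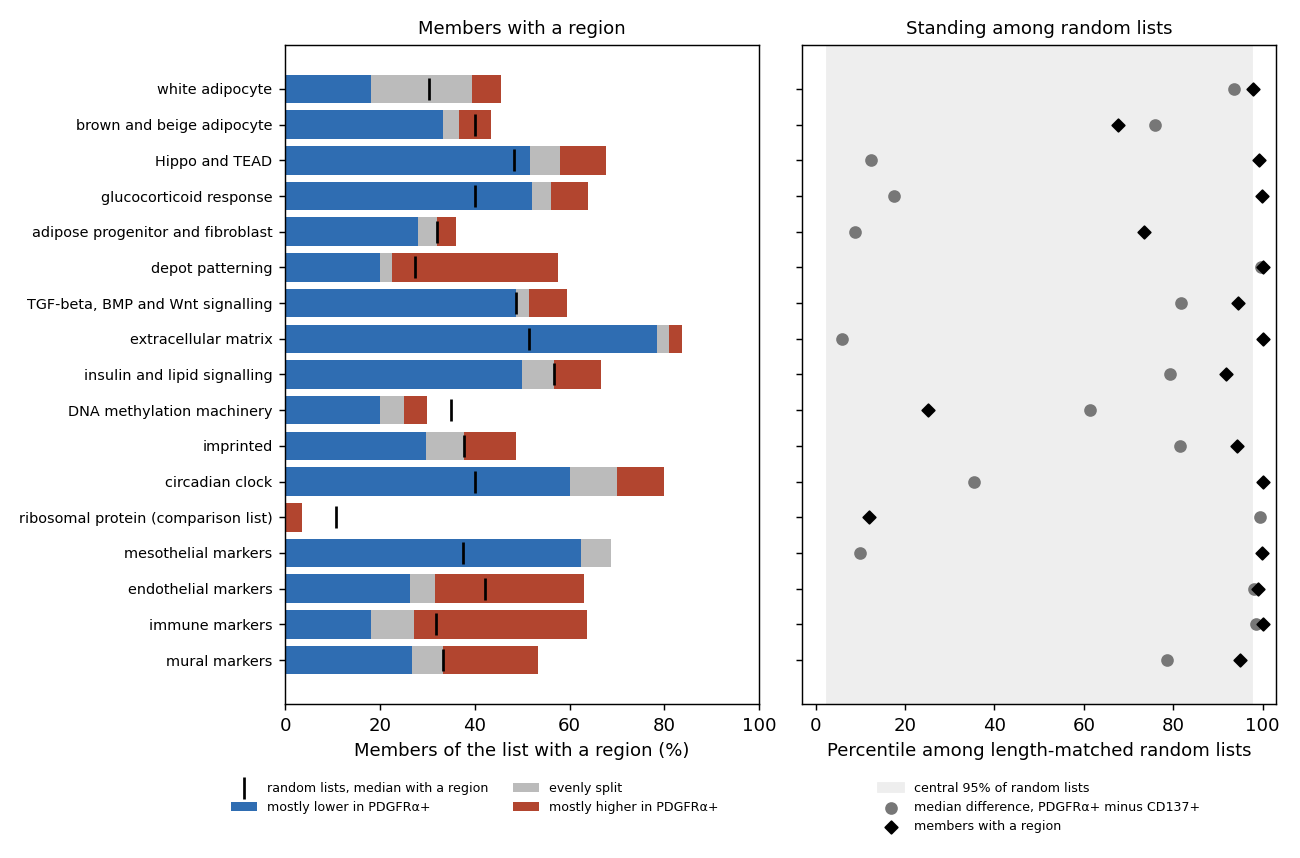
Left, percentage of each list's members that had a region, coloured by whether their regions were mostly lower, evenly split or mostly higher in the PDGFRα+ library, with a vertical tick at the median of the random lists. Right, percentile of each list among 10000 length-matched random lists for members with a region (diamonds) and for the median difference (circles), where the depot patterning list stood at the 99.7 percentile and the extracellular matrix list at the 5.94 percentile in median difference.

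Of the markers of other cell types, the immune and the mural markers held more regions that were higher than lower in PDGFRα+ cells. Of 22 immune markers 14 had a region, at the 99.99 percentile, with 8 mostly higher, 4 mostly lower and 2 split, and 24 of their 34 regions (70.6%) were higher, at the 99.4 percentile. Ptprc, which encodes the pan-leukocyte antigen CD45, was higher in 8 of 8 regions (mean level 0.861 in PDGFRα+ and 0.359 in CD137+), Ikzf1, a lymphoid transcription factor gene, in 5 of 5 (0.915 and 0.387) and Laptm5 in 3 of 3 (0.770 and 0.185). Ptprc and Ikzf1 thus gave 8 and 5 of the 24 higher regions. Runx3 was lower in 5 of 5 (0.210 and 0.879), Mrc1, Itgal and Cd3e were lower in their only regions, and Spi1 and Cd74 were split. The median difference of the immune list was 0.392, at the 98.5 percentile. This call was lost with differences of at least 0.5, where the median was 0.0888, and with gene ends only, where it was 0.427.

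Endothelial markers had regions in 12 of 19 genes, at the 99.0 percentile, with 18 regions higher and 18 lower. Eng was higher in 2 of 2 regions (0.916 and 0.199), Erg in 5 of 8, while Flt4 and 6 of 7 regions of Flt1 were lower. The median difference, 0.0829, stood at the 98.1 percentile. Each of these calls was kept in 5 of 10 alternatives, and with differences of at least 0.5 the number of members with a region stood at the 50.7 percentile. Mesothelial markers had regions in 11 of 16 genes, at the 99.9 percentile, with 10 mostly lower and none mostly higher, including Cldn15 (0.175 in PDGFRα+ and 0.814 in CD137+), Upk1b, Krt7 and Krt19. The call on members was lost with the larger statistics only (97.2 percentile), and the share of higher regions and the median difference, at the 9.80 and 9.90 percentiles, lay inside the central 95%. Mural markers had regions in 8 of 15 genes, with 13 regions higher and 10 lower, and both this share of higher regions (56.5%, at the 95.7 percentile) and the number of genes lay inside the central 95% of random lists. Acta2 was lower (0.148 and 0.723), Tbx2 was higher in 5 of 5 regions (0.803 and 0.302), Myocd was higher in 3 of 4 and Ebf1 was split, and the median difference stood at the 78.5 percentile. In members with a region the mural list lay above the central 95% in 3 of 10 alternatives, and with gene ends only its median difference turned from -0.208 to 0.383. The mesothelial, endothelial and mural lists each share 1 gene (Wt1, Eng and Ebf1) with another list.

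Chromosome X held far fewer regions than any autosome. It had 365 regions, or 2.14 per Mb, against 9.11 to 13.8 per Mb over the 19 autosomes, 5.28 times fewer than the autosomal 11.3. On chromosome X the median absolute difference was 0.5996, above the 0.512 to 0.534 of the autosomes, and the median region held 6 cytosines against 9. Chromosome Y held 2 regions, at 44055505 to 44055731 (0.405 in PDGFRα+ and 0.961 in CD137+) and at 90829223 to 90829321 (0.928 and 0.688). The share higher in PDGFRα+ was 21.1% on X (Wilson interval 17.2 to 25.6) and over the autosomes ranged from 19.3% on chromosome 12 to 26.7% on chromosome 11. Chromosome lengths were taken as the last gene or region position.

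**Figure D4:**
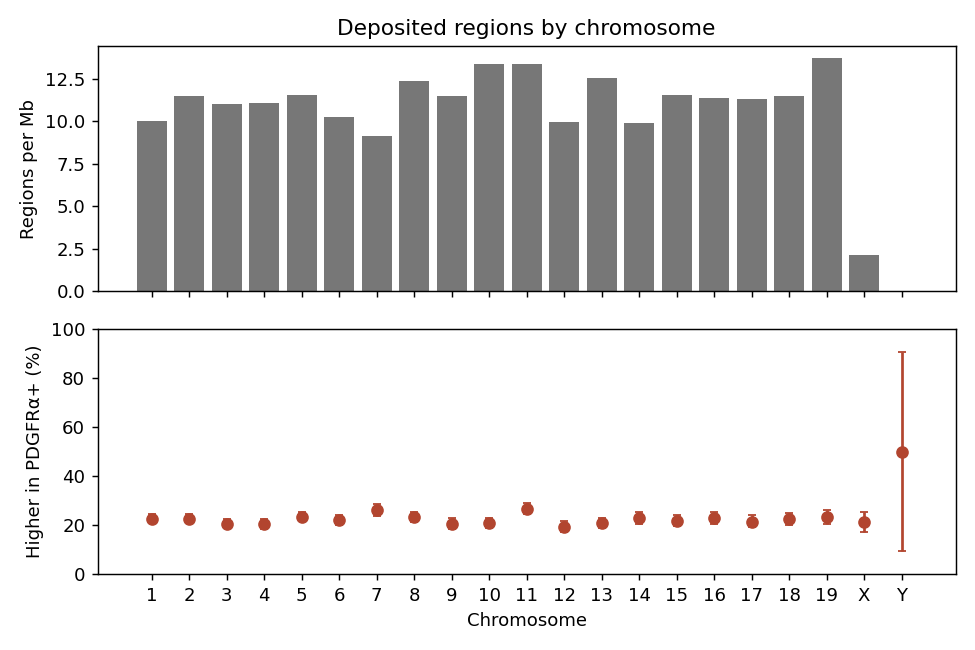
Regions per Mb (top) and percentage of regions higher in the PDGFRα+ library with 95% Wilson intervals (bottom) for each chromosome. Chromosome X stood at 2.14 regions per Mb, below every autosome, and the wide interval of Y rests on 2 regions.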

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

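The settings of gene body only, gene ends only (within 2 kb of either end), 10 kb on either side for marker lists and leaving out regions with 1 library below 0.02 were chosen after the data were seen. Of the values that answer a comparison, 78 kept within their interval or within 1.5 times their count and 30 moved. For single lists, 305 outcomes stayed the same, which includes lists that were not called and stayed so. Of the other outcomes, 22 calls were lost, 12 were gained and 1 reversed. That was the ribosomal list with 10 kb on either side, where the median difference went from 0.644 to -0.198, at the 76.6 percentile, and 2 members had a region. With gene ends only the medians of 4 lists that were not called turned positive (white adipocyte 0.0679, brown and beige 0.0754, insulin 0.411, mural 0.383). The white, the brown and beige and the insulin medians then rested on just 7, 2 and 4 members. Keeping differences of at least 0.5 gave 20.3% of regions higher, median differences of 0.574 and -0.583 (by construction), 5 Tead1 regions with 3 higher, and 0 pathway lists and 0 marker lists above random lists in median difference. Regions with an absolute statistic above the median gave 21.2% higher, -0.535 for lower regions, 53.5% in protein-coding spans and 4.17% within 2 kb of a gene. Weighting by length gave 20.4% higher, and weighting by cytosines gave 0.504 and -0.525. At least 5 cytosines gave -0.524 (-0.5235), and at least 10 gave 0.504 (0.50365), -0.524, 53.7% in protein-coding spans, 4.19% within 2 kb and 1 marker list above in median difference. Flanks of 1 and 5 kb held 2.52% and 9.45% of regions, by construction. Of the 8 genes with most regions, 0 were shared with the top 8 per 100 kb. With gene ends only, 3 pathway lists were above in members with a region, 1 pathway list and 0 marker lists in median difference. With 10 kb on either side, 1 pathway list was above and 1 below in median difference, the latter glucocorticoid response at the 2.10 percentile. Without length matching 1 marker list was above in median difference, and with gene body only also 1. Except where the construction shows it, the cause was not tested. Regions per promoter, by the authors' gene names and by sequence context were not run, since strand, gene names and context were not used here. Depth is unknown, so its effect on the levels could not be measured.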

Other observations

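All tests below except that of the added pan-haematopoietic list were chosen after the result was seen, and the added lists and the Hox clusters were chosen after the values of the fixed lists were seen.

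The 4 Hox clusters, whose genes set position along the body axis, differed in direction. The Hoxd cluster (chromosome 2, 74668225 to 74765142) held 12 regions, all higher in PDGFRα+, with mean levels of 0.822 in PDGFRα+ and 0.346 in CD137+. Hoxb held 8 higher and 1 lower and Hoxc 4 higher and 1 lower. The Hoxa cluster (chromosome 6, 52155367 to 52260880) held 2 higher and 15 lower, with mean levels of 0.295 and 0.648.

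Among the added lists, fibroblast transcription factor genes had regions in 20 of 28 members, at the 99.995 percentile, 13 mostly lower and 6 mostly higher in PDGFRα+, with a median difference at the 84.8 percentile. Macrophage genes had regions in 7 of 30 members, 5 mostly higher, and 8 of their 11 regions were higher, at the 98.1 percentile, while their median difference stood at the 93.7 percentile. T cell genes (13 of 25 with a region), B cell genes (9 of 20), mast cell genes (5 of 14) and neural and Schwann cell genes (8 of 15) had median differences at the 88.3, 65.5, 26.9 and 43.1 percentiles. Most T cell regions (25 of 38) and B cell regions (11 of 15) were lower in PDGFRα+, with 7 T cell genes mostly lower and 4 mostly higher, and 6 B cell genes mostly lower and 3 mostly higher. Their shares of higher regions stood at the 77.9 and 61.5 percentiles, inside the central 95%.

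In the immune list 24 of 34 regions were more methylated in the PDGFRα+ library, and 8 of the 14 genes with a region were mostly higher. Fewer cells of the main type in the CD137+ library, raising every other type alike, stays open. The shares of higher regions in the 4 marker lists spread over 63.4 percentage points, at the 98.6 percentile of random lists. Without the immune list they spread over 49.4, at the 95.4 percentile and inside the central 95%. The mesothelial share, 7.14%, lay below the 22.3% of all regions, while the shares of the other marker lists lay above it. At the 9.80 percentile the mesothelial share lay inside the central 95%, so it does not settle the question. Haematopoietic cells in the CD137+ library may be a source, but the test on the pan-haematopoietic list cannot decide it. This list, which shares no gene with the immune list, had a median difference at the 99.95 percentile. However, 85 of its 137 regions were lower and its share of higher regions stood at the 95.6 percentile, inside the central 95%. A difference between the progenitor types or depots at blood cell genes would raise the pan-haematopoietic list too. With haematopoietic cells as the source, mean levels at Ptprc, Ikzf1 and Laptm5 would need 58.3%, 57.7% and 76.0% of the CD137+ library's cells unmethylated there. That holds if its other cells had the levels of the PDGFRα+ library. Sorting for CD137 would not remove cells that carry CD137. A difference between the progenitor types or depots themselves stays open and untested, and how many of these genes the cultured cells express is not known here.

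The 81 regions with 1 library below 0.02 (27 higher and 54 lower in PDGFRα+) had a median length of 181 bases, and 27 of the 100 regions with the largest absolute statistic were of this kind. Single unconverted or methylated fragments at low depth might give such regions, but 5 of them were longer than the 350 bases of the fragments and the longest spanned 423. At equal cytosine density the class was also longer than the other regions in each of 4 density classes (medians of 153 to 225.5 bases against 57 to 91). A prediction written after the result was seen took a limit set by the fragments to make it shorter. But the class also held more cytosines in each density class (medians of 16 to 47 against 9 to 25), and the densest held just 8 other regions. At equal density more cytosines make a longer region, so this comparison cannot decide. Since depth is unknown, single fragments and a difference between the cells cannot be told apart.

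Chromosome X held few regions. Lower read depth on a single X might account for it, but depth is unknown. The median absolute difference on X, 0.5996, was above that of every autosome. It was also above them when autosomal regions were drawn to the cytosine numbers of X (0.510 to 0.544). Low depth was taken to give this, by a prediction written after the result was seen. A biological difference of X could give it too, so the value cannot decide. A biological difference of X was not tested.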
